A study of Mus musculus with 23 samples.

How the data were processed

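RNA-seq of 23 mouse libraries was used, 12 from sorted PSCs and 11 from sorted organoids of co-cultures in Matrigel, with RNA taken up in TRIzol and purified with a PureLink kit per the labels' protocols. The deposited tables hold 1 estimated count (expected count) per transcript and library, made by the authors with Salmon 1.9.0 against the mouse build GRCm39 (mm39), per the submitters' processing notes. The library kit, strandedness, read length and transcript annotation of the submitters are not given in the sources used here. Estimated counts are shares of reads that a model assigns to transcripts, so genes with a near-identical copy can take each other's reads, and predicted genes and pseudogenes were not among the named genes.

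Each table lists 117135 transcripts, of which 115973 (99.0%) were matched by identifier to the GENCODE M21 annotation, used for gene names only because its build differs from the submitters'. Unmatched transcripts held 0.364 to 0.443% of reads per library and were left out of library sizes and tests. Estimated counts were summed over the transcripts of each of 35523 genes (21784 protein-coding) and rounded to whole numbers. Total depth lay between 21823084 and 34828131 estimated counts per library, and no table holds columns of other samples.

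Libraries were grouped by the genotype and cell type in the labels, and the co-culture and PSC line were read from the titles. Counts of every pair of libraries of 1 group were compared by a chi-square test. The lowest ratio of chi-square to degrees of freedom was 10.9 (organoid KO libraries 11 and 12), so no pair agreed within sampling noise and all were kept. Libraries are named by the leading numbers of their titles, and no number is shared between groups, so no pairing by number was made. Co-culture was the block because each KO library has a WT library with the same organoid line and PSC parent.

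The following choices were made before the data were examined, including the tests, the gene lists and the rule for named genes. Genes were tested with edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr, robust dispersion estimation, glmQLFit and glmQLFTest. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05, and an adjusted p in the text comes from this test unless camera or another tool is named. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM values use TMM library sizes, and group means are given with the SD over libraries. The PSC fit used the 12 PSC libraries and the organoid fit the 11 organoid libraries, each with co-culture as a block, leaving 7 and 6 residual degrees of freedom. The test between fractions used all 23 libraries with genotype and co-culture within each fraction. WT PSC and organoid libraries were compared with co-culture as a block, the PSC4 and PSC5 effects by an interaction in the PSC fit, and clones A3 and B4 over 6 libraries with organoid line as a block. Egfr was also tested alone by an exact permutation test of mean log2(CPM + 1).

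Named genes are Egfr and, per direction, the 10 genes with the largest log2 fold change among protein-coding genes with an adjusted p under 0.05, a mean log2 CPM of at least 1 and KO means on the same side of WT in all 4 co-cultures. Predicted genes were left out, and other comparisons name 5 genes per direction. From each list up to 4 measured members with the smallest p were open to naming, and Epcam, Krt19, Col1a1, Pdgfrb, Acta2 and Il6 were open to naming in any comparison. Some genes that these rules allow are not reported here. Differences per library and co-culture were taken on log2(CPM + 0.5). For the comparison of fractions, a gene with 0 counts in a group was set to 3 counts over the group, a limit that covers counting error only.

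The 26 gene lists were tested with camera in limma 3.58.1 on voom values of the same designs, at a preset inter-gene correlation of 0.01, with adjustment over the lists. Camera with an estimated correlation and fry, which tests each list by itself, stood beside it. By fry 0 lists passed in PSCs and 14 in organoids, and in its test for change in either direction 1 and 21 passed. Each list's members were also adjusted over the list alone. Shares of the other cell type in a fraction were estimated as the median, over marker genes of at least 50 CPM in their own fraction, of the level in the other fraction as a percent of the level in the own fraction. Principal components were taken from log2 CPM of genes with a mean of at least 1, and shares of variance are those each factor holds alone.

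These tests were tested on simulated data drawn from the real means and library sizes, with 200 genes changed by known folds. Each library was drawn by itself, without a level shared by libraries of 1 PSC line. Real PSC libraries of 1 line correlated at 0.726 after genotype and co-culture. The shares recovered and falsely called therefore do not cover the spread between PSC lines. In the PSC design (13895 genes) the test recovered 25.8% of genes changed 1.5-fold, 64.5% of those changed 2-fold and 89.1% of those changed 4-fold, with 5.0% false calls. In the organoid design (13789 genes) these were 69.0%, 79.7% and 95.5%, with 6.5% false calls. In the test between fractions (14542 genes) they were 19.4%, 54.7% and 79.2%, and in the comparison of WT fractions (14190 genes) 0%, 11.4% and 68.3%. They were, for clones A3 and B4 (13428 genes) 54.5%, 77.4% and 98.5% with 16.3% false calls, and for PSC4 against PSC5 (13398 genes) 0%, 0% and 31.4%. A cell cycle list lowered by 0.5 on the log2 scale in simulated PSC data was called as 1 of 26 lists, with 0 others. The genes were drawn independently of each other, so this does not test false calls of lists whose members vary together.

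Alternatives were RLE size factors, DESeq2 1.42.0, no low-count filter, a filter of at least 1 CPM in 4 libraries, an effective-length offset and no block. Others were counts summed per PSC line, PSC line as a random effect in limma, markers of the other cell type as a covariate, subsets of co-cultures, a fold minimum, and leaving out each library in turn. Further alternatives were chosen after seeing the data, namely leaving out clone A3 or B4, T6-LOH co-cultures only in the organoid test, summed counts without T69A, and limma without the random effect. They also include genes expressed in both fractions, lists with the covariate or without a clone, and organoid libraries thinned to the lowest PSC depth. The last are culture as a block in the test between fractions, with both fractions of 11 cultures (22 libraries), and Egfr tested with genotypes reassigned within co-cultures. The comparisons between organoid lines within PSC4 in the closing part were also chosen after seeing the data. Other splits of the libraries were refitted up to 100 times per comparison, and in the test between fractions genotypes were also assigned to whole cultures in all 54 ways. List calls were also counted, and the mitochondrial share tested by exact permutation, with genotypes reassigned within co-cultures, after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.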

Results

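RNA-seq was read from both cell fractions of mouse co-cultures of pancreatic stellate cells and pancreatic tumour organoids. Pancreatic stellate cells (PSCs) are resident cells of the pancreas that can become fibroblasts around a tumour, and organoids are tumour cells grown as small three-dimensional structures in a gel. PSCs and organoids shared Matrigel, a basement membrane extract, for 3.5 days in reduced or control medium and were then separated by flow sorting. The PSCs were either Egfr wild type (WT, carrying the name Rosa in the labels) or Egfr knockout (KO) clones, and the organoids were not described as edited. Egfr encodes the receptor for epidermal growth factor and its relatives.

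The series holds 23 libraries. The PSC fraction has 4 WT and 8 KO libraries, and the organoid fraction has 4 libraries grown with WT PSCs and 7 grown with KO PSCs. They come from 4 co-cultures, each an organoid line with a PSC parent line, namely T6-LOH with PSC4, T6-LOH with PSC5, T12-LOH with PSC4, and T69A with PSC4. Each co-culture has 1 WT library and a library for each of 2 KO clones, A3 and B4 from PSC4 or C5 and D4 from PSC5. The exception is T69A with clone A3, whose organoid library was not analysed here. The 12 PSC libraries therefore represent 6 PSC lines and 3 organoid lines. The labels do not say that libraries came from separate cultures, so each p-value measures only the spread between these libraries, and libraries of 1 clone are not separate clones. Depth lay between 21823084 and 34828131 estimated counts in PSC libraries and between 23814409 and 34643087 in organoid libraries. Mitochondrial transcripts took 1.96 to 2.9% of counts in PSC libraries and 2.11 to 4.96% in organoid libraries, with the highest share in organoid WT library 2 (T69A). In PSCs the share was 2.16% ± 0.2 in WT (SD, n = 4) and 2.61% ± 0.238 in KO (SD, n = 8). It was above the own control in 7 of 8 KO libraries, all but library 24. The mean difference within co-cultures was 0.449 percentage points (exact permutation p = 0.037 over 81 assignments, smallest possible 0.0123). These assignments treat libraries of 1 PSC line as separate, so chance between the PSC lines is not excluded. In organoids the mean difference was -0.339 (exact permutation p = 0.852 over 54 assignments), with 4 of 7 libraries above their control.

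Egfr was lower in all 8 KO PSC libraries than in the WT library of their own co-culture, by amounts that differed between clones. In WT PSCs Egfr stood at 287 CPM (counts-per-million, scaled by library size) with T6-LOH (library 20), 297 with T12-LOH (23), 328 with T69A (17) and 427 in PSC5 (26). Clone A3 held 59.7 CPM with T6-LOH (library 21), 105 with T12-LOH (24) and 102 with T69A (18), or 20.8%, 35.4% and 31% of its own control. Clone B4 held 118 CPM with T6-LOH (library 22), 220.4 with T12-LOH (25) and 199.7 with T69A (19), or 41.2%, 74.1% and 60.8%. In PSC5, clone C5 (library 27) held 112 CPM, 26.3% of control, and clone D4 (library 28) held 352 CPM, 82.4% of control. The group means were 335 ± 63.9 CPM in WT PSCs (SD, n = 4) and 159 ± 94.5 CPM in KO PSCs (SD, n = 8). The difference in mean log2 CPM was -1.25. The 2-sided exact permutation p was 0.0162 over 495 splits of all libraries and 0.0247 over 81 assignments within co-cultures. Both tests treat libraries of 1 PSC line as separate, so chance between the PSC lines is not excluded. In the gene-wide edgeR quasi-likelihood test with co-culture as a block, the Egfr difference was -1.15 (SE 0.34) with a Benjamini-Hochberg adjusted p of 0.225. How Egfr was disrupted is not given in the sources used here, and a disrupted allele can still make mRNA, so these levels are a partial check of the labels.

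In organoid fractions Egfr stood at 92.6 CPM (library 6), 116 (14), 84.1 (10) and 148 (2) with WT PSCs. With KO PSCs it stood at 74.3 CPM (library 7), 86.1 (8), 73.4 (11), 87.2 (12), 129 (4), 89.1 (15) and 83.1 (16). The group means were 110.0 ± 28.5 CPM (SD, n = 4) and 89.0 ± 18.9 CPM (SD, n = 7). Mean log2 CPM differed by -0.29, with a 2-sided exact permutation p of 0.158 over 330 splits that ignore co-culture. Within co-cultures the mean difference was -0.22, with an exact permutation p of 0.0556 over 54 assignments (smallest possible 0.0185). The edgeR test with co-culture as a block gave -0.23 (SE 0.07, unadjusted p = 0.00565, adjusted p = 0.0523), and 6 of 7 libraries lay below their own control.

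**Figure D1:**
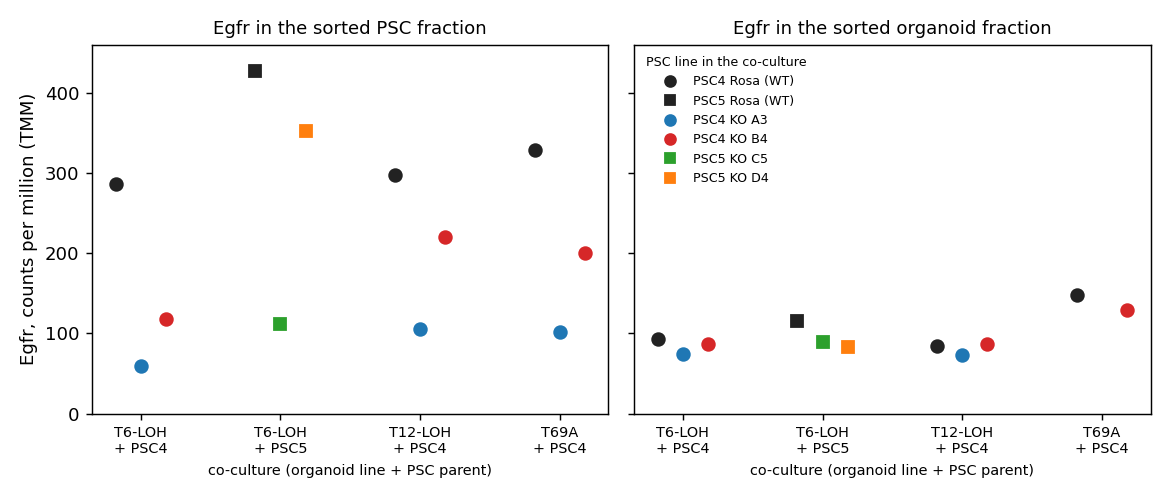
Egfr in counts-per-million (vertical axis) in each library, by co-culture, for the sorted PSC fraction and the sorted organoid fraction; each point is 1 library, coloured by the PSC line in the culture. All 8 KO points in the PSC fraction lie below the WT point of their co-culture, from 20.8% (A3 with T6-LOH) to 82.4% of it (D4).

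The libraries grouped first by cell line within each fraction. Among PSC libraries the first principal component held 35.5% of the variance and separated clone B4 from the other PSC4 lines, and the second, with 23.6%, separated PSC5 from PSC4. PSC line alone accounted for 75.2% of the variance and genotype for 14.9%. Genotype is fixed by PSC line, so the share of PSC line contains that of genotype. PSC line also divides the libraries into more groups, which by itself raises its share. The shares therefore do not rank PSC line against genotype. Among organoid libraries the first 2 components, with 54.7% and 29.2%, separated the 3 organoid lines, organoid line alone accounted for 83.6% of the variance, and the PSC genotype for 5.1%. These shares were not adjusted for the number of groups, which was larger for organoid line than for genotype.

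**Figure D2:**
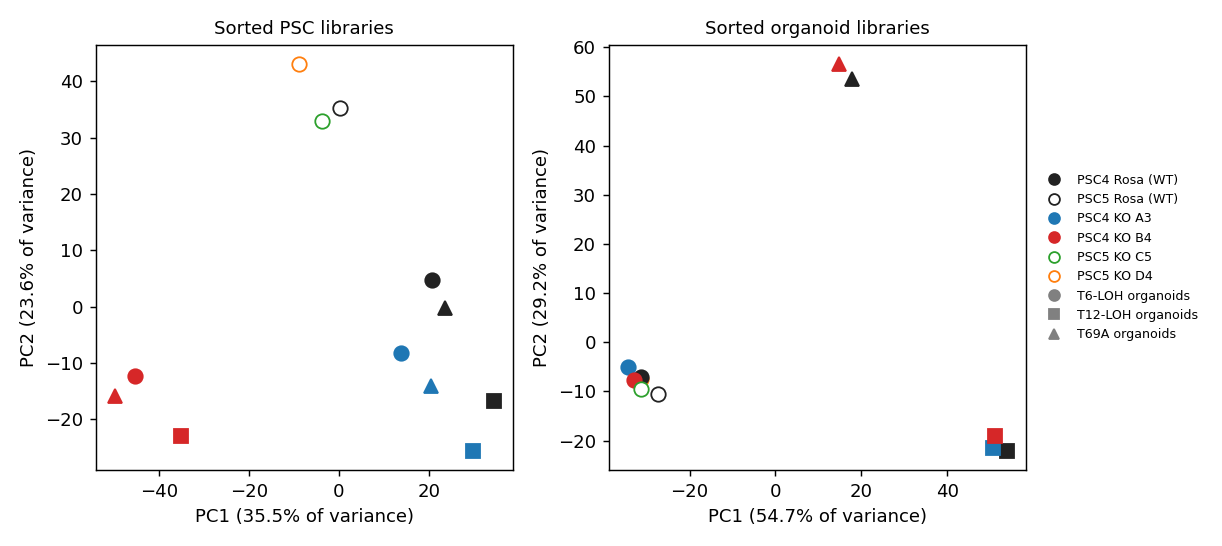
First and second principal components (axes, with the share of variance each holds) of log2 CPM in PSC libraries and organoid libraries; each point is 1 library, coloured by PSC line with PSC5 lines open, and shaped by organoid line. PSC libraries part by PSC line (first component 35.5%) and organoid libraries by organoid line (first component 54.7%).

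The first comparison asked which genes differ between Egfr KO and WT PSCs grown with the same organoids. KO PSCs held less mRNA of 2 genes of glucose use, Aldoc and Slc2a3, and of Glul and Gda, and more of Smad9, Nr1d1 and Pdk4. Aldoc encodes a glycolytic aldolase and Slc2a3 a glucose transporter, while Glul makes glutamine and Gda breaks down guanine. Smad9 transmits bone morphogenetic protein signals, Nr1d1 is a repressor of the circadian clock, and Pdk4 is a kinase that restrains pyruvate entry into the mitochondria. Each of these 7 genes moved the same way in 8 of 8 KO libraries against the WT library of the same co-culture. The rule for named genes asked for KO means on the same side of WT in every co-culture, so selection largely fixed this agreement. KO libraries of the same co-culture also share their WT library, so these are not 8 separate checks.

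Aldoc fell from 10.3 ± 3.74 CPM (SD, n = 4) in WT to 0.908 ± 0.783 CPM (n = 8) in KO PSCs, with a log2 fold change of -3.67 (SE 0.32) and an edgeR adjusted p of 0.0114. Slc2a3 fell from 16.6 ± 4.11 to 3.84 ± 1.87 CPM, a log2 fold change of -2.13 (SE 0.26, adjusted p = 0.0347). Gda fell from 265 ± 105 to 153 ± 56.9 CPM (log2 -0.81, SE 0.08, adjusted p = 0.0136). Glul fell from 93.1 ± 11.7 to 58.8 ± 6.88 CPM (log2 -0.67, SE 0.08, adjusted p = 0.0358). Smad9 rose from 8.20 ± 3.43 to 21.0 ± 9.37 CPM (log2 1.30, SE 0.15, adjusted p = 0.0259). Nr1d1 rose from 24.1 ± 6.67 to 57.2 ± 16.4 CPM (log2 1.25, SE 0.16, adjusted p = 0.0369). Pdk4 rose from 27.6 ± 8.34 to 52.9 ± 18.8 CPM (log2 0.92, SE 0.11, adjusted p = 0.0292). In total 9 of 14107 tested genes passed, 3 higher and 6 lower, with 1937 genes at an unadjusted p under 0.05. The other two lay outside the rule for named genes and were singled out after their values were seen. They were Ccdc36 (1.65 to 0.148 CPM, log2 -3.46, adjusted p = 0.0136) and the homeobox gene Nkx2-3 (3.22 to 0.291 CPM, log2 -3.64, adjusted p = 0.0482), which did not differ in T6-LOH with PSC5.

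This count depended on the test and on single libraries. DESeq2 called 586 genes (256 higher, 330 lower). Counts summed per PSC line, PSC line as a random effect in limma, and the set without T69A each gave 0 genes. It was 0 without WT library 20, WT library 23 or KO library 21, 1 without WT library 17, 4 without KO library 24 or 25, and 5 without KO library 22. It was 20 without KO library 27 or 28, and 51 without WT library 26. All these counts are after adjustment, so the 1937 genes at an unadjusted p under 0.05 in the edgeR test of all libraries are no measure of them.

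Of 26 gene lists fixed beforehand, 4 were lower in KO PSCs as sets by camera, which compares a list with all other genes at a preset correlation of 0.01. The mitochondrial share of counts was higher in 7 of these 8 KO libraries, and no list test accounts for it. The cholesterol synthesis list was the lowest by this test (adjusted p = 1.8e-12), but with an adjusted p = 0.523 with an estimated correlation. None of its 25 measured members passed over all genes, 15 of 25 were lower and 0 higher when adjusted over the list alone, and the list mean was below the own control in 8 of 8 libraries. Means lower in 8 of 8 libraries do not set the called lists apart. They were also found for the uncalled antigen-presenting CAF and mesothelial, epithelial-mesenchymal transition and fibroblast lists. Fdps, an enzyme of the isoprenoid branch, was at 256 ± 51.0 CPM in WT and 128 ± 40.5 CPM in KO (log2 -1.01, adjusted p = 0.148). The regulator Srebf2 was at 690 ± 70.6 and 481 ± 84.9 CPM (log2 -0.52, adjusted p = 0.193). Further members were Pmvk (log2 -1.12, adjusted p = 0.208) and Acat2 (log2 -0.38, adjusted p = 0.148). The glycolysis and hypoxia list was lower (camera adjusted p = 6.5e-06, and adjusted p = 0.523 with an estimated correlation), and its mean was lower in 8 of 8 libraries. Aldoc was the 1 of 28 members that fell over all genes, and 2 were lower adjusted over the list alone. The lactate exporter Slc16a3 was at 92.0 CPM in WT and 31.2 CPM in KO PSCs (log2 -2.37, adjusted p = 0.156). Eno2 was at log2 -0.32 (adjusted p = 0.229) and Ndrg1 at -0.56 (adjusted p = 0.253).

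Markers of inflammatory cancer-associated fibroblasts (CAFs), the cytokine-secreting fibroblasts of a tumour, were lower as a set (camera adjusted p = 0.000961, and adjusted p = 0.523 with an estimated correlation). Of its 29 measured members 0 passed over all genes, 3 were lower adjusted over the list alone (Il11, Has1 and Dpt), and the list mean was lower in 8 of 8 libraries. Il11, a cytokine, was at log2 -1.34 (adjusted p = 0.145), the hyaluronan synthase Has1 at -2.23 (adjusted p = 0.148), and Dpt at -2.22 (adjusted p = 0.17). Il6 was at 135 ± 72.8 CPM in WT against 71.6 ± 41.4 CPM in KO (log2 -0.98, adjusted p = 0.246, lower in 7 of 8).

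Interferon-stimulated genes, which cells switch on against viruses, were lower as a set (camera adjusted p = 1.1e-07, and adjusted p = 0.586 with an estimated correlation). None of 34 members passed over all genes, and 0 passed adjusted over the list alone. Their mean was lower in 6 of 8 libraries and higher in both T12-LOH libraries, from -2.11 to 0.77 on the log2 scale. Rsad2 was at log2 -1.90 (adjusted p = 0.162), Cmpk2 at -1.79 (adjusted p = 0.241) and Gbp7 at -1.02 (adjusted p = 0.197). The number of lists called in PSCs was 7 without KO library 18 or 25, 8 without KO library 19, 9 without WT library 26 and 11 without KO library 27.

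EGFR and MAPK feedback targets, which are switched on by signalling downstream of the receptor, did not pass as a set in PSCs (median log2 -0.03, camera adjusted p = 0.923). Over all genes 0 of 30 passed, and 0 adjusted over the list alone. Spry1 stood at log2 1.09 (adjusted p = 0.254), Spry4 at 0.64 (adjusted p = 0.281), Il1rl1 at -2.03 (adjusted p = 0.148) and Areg at -0.90 (adjusted p = 0.294). The EGFR ligand and receptor list also gave 0 of 12 both ways (camera adjusted p = 0.103), with Tgfa at log2 -0.96 (adjusted p = 0.285) and Nrg2 at 0.81 (adjusted p = 0.241). Myofibroblastic CAF markers, the contractile and collagen genes, had a median of 0.26 with 0 of 29 passing both ways (camera adjusted p = 0.0814). Among them Acta2, smooth muscle actin, was at 176 ± 128 CPM in WT and 329 ± 176 CPM in KO PSCs (log2 1.16, adjusted p = 0.243, higher in 7 of 8). Myl9 was at log2 1.22 (adjusted p = 0.198), and Col1a1 at 6178 and 6204 CPM (log2 -0.02, adjusted p = 0.974).

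For the following lists 0 members passed over all genes and the camera test did not pass. TGF-beta targets (30 measured, camera adjusted p = 0.176), matrix remodelling enzymes (30, adjusted p = 0.841), JAK-STAT3 targets (17, adjusted p = 0.841), and ATF4 and unfolded protein response genes (28, adjusted p = 0.189) had 0 adjusted over the list alone. So did p53 targets (25, adjusted p = 0.0752), YAP and TEAD targets (23, adjusted p = 0.195), and the classical (16, adjusted p = 0.548) and basal-like (13, adjusted p = 0.176) tumour programmes. Adjusted over the list alone, 2 of 40 cell cycle genes were higher (Rrm2 and Ccne1; camera adjusted p = 0.0852). Of 27 NF-kappaB targets 1 was lower in this way (Nfkb1, 252 CPM in WT and 170.1 CPM in KO, log2 -0.56; camera adjusted p of the list = 0.0816). Likewise 1 of 9 antigen-presenting CAF and mesothelial markers (Msln; camera adjusted p = 0.0984) and 1 of 27 epithelial-mesenchymal transition genes (Twist2; camera adjusted p = 0.0814) were lower. Of 15 Wnt and Hedgehog targets 3 were higher (Notum, Gli1 and Foxf1) and 1 lower (Ptch1) adjusted over the list alone (camera adjusted p = 0.179).

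Markers of other cell types did not move as sets in the PSC fraction. Of 20 measured epithelial markers 0 passed both ways (median log2 0.02, camera adjusted p = 0.578 with a downward direction). Epcam was at log2 -0.12 (adjusted p = 0.881) and Krt19 at 0.31 (adjusted p = 0.53). The organoid share of the PSC fraction, estimated from epithelial markers, was 0.276% ± 0.262 (SD, n = 4) in WT and 0.279% ± 0.233 (SD, n = 8) in KO libraries. It lay between 0.549 and 0.72% in all 3 T69A libraries. Fibroblast markers gave 0 of 23 over all genes and 3 lower adjusted over the list alone (Lum, Dcn and Twist2; camera adjusted p = 0.0814). Pdgfrb was at log2 -0.14 (adjusted p = 0.72). Immune (2 measured, camera adjusted p = 0.415), endothelial (8, adjusted p = 0.996), acinar and endocrine (1, adjusted p = 0.996) and neural and muscle markers (4, adjusted p = 0.49) had 0 members passing both ways.

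The second comparison asked which genes differ between organoids grown with KO PSCs and the same organoid lines grown with WT PSCs. By camera, cell cycle genes were higher as a set in organoids grown with KO PSCs (14 of 40 members rose). Lower as sets were TGF-beta targets (8 of 23 members fell), YAP and TEAD targets (6 of 22), glycolysis and hypoxia genes (6 of 29) and matrix remodelling enzymes (3 of 18). With an estimated correlation 0 lists passed, with an adjusted p of 0.345 to 0.363 for these 5, and the PSC share of the organoid fractions was lower beside them (0.0286% against 0.0804%). Mki67, a marker of dividing cells, rose in 7 of 7 libraries, while Vegfa, the main angiogenic growth factor, and Ccn2, a YAP and TGF-beta target, fell in 7 of 7. Mki67 went from 357 ± 12.6 CPM (SD, n = 4) to 439 ± 34.8 CPM (SD, n = 7), with a log2 fold change of 0.28 (SE 0.05) and an edgeR adjusted p of 0.0104. Vegfa fell from 422 ± 112 to 273 ± 61.8 CPM (log2 -0.67, SE 0.08, adjusted p = 0.00344). Ccn2 fell from 518 ± 65.5 to 386 ± 53.8 CPM (log2 -0.40, SE 0.08, adjusted p = 0.0156).

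Of 13939 tested genes 1441 changed, 597 higher and 844 lower, which is 10.3%, and 4054 had an unadjusted p under 0.05. Most changes were small, with a median absolute log2 fold change of 0.304. At least 2-fold changes were seen in 90 genes, 22 higher and 68 lower. Without co-culture as a block edgeR called 0 genes. With fibroblast markers as a covariate it also called 0, with 1023 at an unadjusted p under 0.05. The median absolute log2 fold change of the 1441 genes was then 0.299 with a median SE of 0.161, against 0.068 before. DESeq2, limma voom and limma with PSC line as a random effect called 1880, 1627 and 1442 genes. The count was 214 without WT library 14, 427 without WT library 2, 440 without KO library 4, and 713 without KO library 16. It was 826 without KO library 7, 844 without KO library 11, 857 without KO library 15 and 886 without WT library 10. It was 37 with counts summed per PSC line, 189 with PSC4 co-cultures only, 445 without T69A and 867 with a length offset.

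Among the genes with the largest rises, Ranbp3l rose from 0.593 to 2.71 CPM (log2 2.08, SE 0.34, adjusted p = 0.00634) and Igfbp5, which binds insulin-like growth factors, from 1.97 to 5.98 CPM (log2 1.69, SE 0.25, adjusted p = 0.00498). The metalloprotease gene Adamts15 rose from 8.29 ± 5.45 to 19.6 ± 13.2 CPM (log2 1.15, SE 0.14, adjusted p = 0.00243). The tight junction gene Cldn8 rose from 11.9 to 25.4 CPM (log2 0.98, adjusted p = 0.0103), and the goblet cell gene Clca1 from 178 ± 105 to 358 ± 221 CPM (log2 0.91, SE 0.20, adjusted p = 0.0375). Ugt2b36 rose by 1.27 on the log2 scale (adjusted p = 0.00894), Cyp4f14 by 1.25 (adjusted p = 0.0109) and Aldh3a1 by 1.04 (adjusted p = 0.00404). Sema3d rose by 1.02 (adjusted p = 0.0348) and C4bp by 0.98 (adjusted p = 0.0359). These 10 genes were higher in 7 of 7 libraries, except C4bp with 6 of 7, and the rule for named genes asked for a higher KO mean in every co-culture.

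Among the largest falls was Has2, which makes hyaluronan, from 6.29 ± 4.84 to 1.98 ± 1.80 CPM (log2 -2.05, SE 0.34, adjusted p = 0.0105). The placental growth factor gene Pgf fell from 18.0 ± 11.9 to 7.67 ± 5.48 CPM (log2 -1.32, SE 0.12, adjusted p = 0.00154). The anchoring collagen gene Col7a1 fell from 28.2 to 11.5 CPM (log2 -1.33, adjusted p = 0.0387) and Spsb1 from 23.2 ± 8.03 to 9.77 ± 3.03 CPM (log2 -1.22, SE 0.18, adjusted p = 0.00783). Nt5e, the adenosine-producing ectonucleotidase, was at log2 -1.64 (adjusted p = 0.0472), and the actin-binding Dbn1 at -1.57 (adjusted p = 0.0483). Hist1h2bq was at -1.32 (adjusted p = 0.0154), the chemokine Cxcl10 at -1.30 (adjusted p = 0.0105) and Pou6f1 at -1.28 (adjusted p = 0.00654). Col1a1 fell from 4.68 ± 4.62 to 1.32 ± 1.12 CPM (log2 -1.45, SE 0.28, adjusted p = 0.0128), against 6033 CPM in PSC libraries. These 10 genes were lower in 7 of 7 libraries, and the rule for named genes asked for a lower KO mean in every co-culture.

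**Figure D3:**
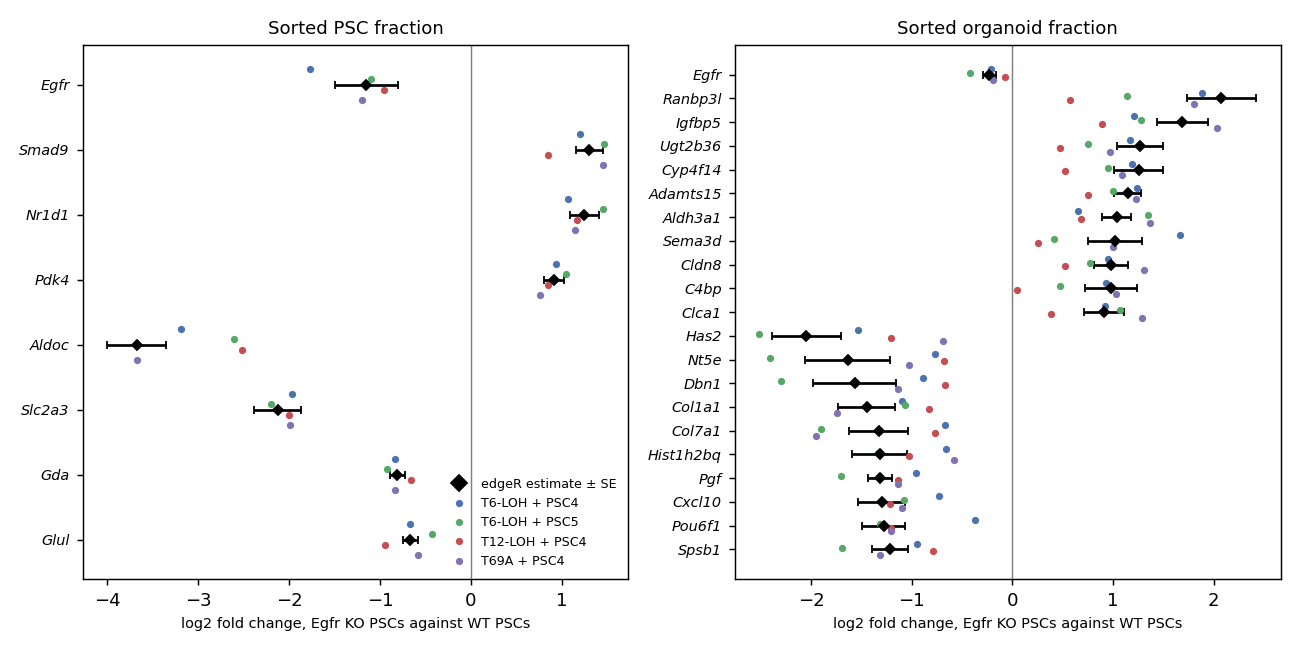
Log2 fold change of the named genes with Egfr KO against WT PSCs (horizontal axis), in the sorted PSC and organoid fractions; diamonds are edgeR estimates with bars of 1 standard error, and dots are the mean KO minus WT difference of each co-culture. The dots of Aldoc, Slc2a3 and Glul in PSCs and of Pgf and Has2 in organoids lie below 0 in all 4 co-cultures, as the rule for named genes required.

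Cell cycle genes rose as a set in organoids (camera adjusted p = 3.2e-11, and adjusted p = 0.363 with an estimated correlation). Of 40 members 14 rose and 0 fell over all genes, 24 were higher adjusted over the list alone, and the list mean was higher in 7 of 7 libraries. The mean of the uncalled classical tumour programme was higher in 7 of 7 as well. With fibroblast markers as a covariate the camera adjusted p of the cell cycle list was 0.000853, while the median log2 fold change of its members went from 0.178 to 0.104 and their median SE from 0.063 to 0.144. Beside Mki67, the cyclin gene Ccna2 rose (log2 0.29, adjusted p = 0.0113), as did Birc5 (0.27, adjusted p = 0.019) and the nucleotide reductase gene Rrm2 (0.33, adjusted p = 0.0242, higher in 6 of 7).

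TGF-beta targets were lower as a set (camera adjusted p = 5.2e-05, and adjusted p = 0.345 with an estimated correlation), with 8 of 23 lower over all genes, 10 lower adjusted over the list alone and 0 higher. Ccn2 was among them, with Tgfb1 itself (log2 -0.32, adjusted p = 0.0333) and Skil (-0.44, adjusted p = 0.0336). YAP and TEAD targets, which respond to stretch and stiffness, were lower (camera adjusted p = 0.000252, and adjusted p = 0.345 with an estimated correlation), with 6 of 22 lower over all genes and 8 adjusted over the list alone. Among these were Gadd45a (log2 -0.80, adjusted p = 0.00644), Dock5 (-0.26, adjusted p = 0.013) and Amotl1 (-0.21, adjusted p = 0.0348). Glycolysis and hypoxia genes were lower (camera adjusted p = 3.4e-05, and adjusted p = 0.363 with an estimated correlation), with 6 of 29 lower over all genes and 13 adjusted over the list alone. Beside Vegfa these were led by Ddit4, an inhibitor of mTOR, from 79.9 to 51.0 CPM (log2 -0.64, SE 0.08, adjusted p = 0.00243), Bnip3 (-0.60, adjusted p = 0.0086) and Slc16a3 (-0.39, adjusted p = 0.0145). JAK-STAT3 targets were lower (camera adjusted p = 0.000889, and adjusted p = 0.353 with an estimated correlation), with 4 of 15 lower over all genes and 6 adjusted over the list alone. They were Pim1 (95.7 to 65.6 CPM, log2 -0.55, adjusted p = 0.00394), Cish (-0.54, adjusted p = 0.00706), Lif (-0.55, adjusted p = 0.0243) and the acute phase gene Saa3 (-2.37, adjusted p = 0.0382). The means of these 4 lists, and of the uncalled p53 list, were lower in 7 of 7 libraries. Fibroblast markers fell beside them, and with these markers as a covariate the calls of YAP and TEAD targets (camera adjusted p = 0.321) and JAK-STAT3 targets (0.0711) were lost. The median log2 fold change of the YAP and TEAD list went from -0.185 to -0.077 and that of the JAK-STAT3 list from -0.153 to -0.135, while the median SE of their members went from 0.077 to 0.183 and from 0.092 to 0.222. TGF-beta targets (0.0104) and glycolysis and hypoxia genes (4.6e-10) were still called, with medians going from -0.294 to -0.219 and from -0.215 to -0.398, and median SEs from 0.1 to 0.24 and from 0.076 to 0.172.

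Matrix and mesenchymal lists were lower beside markers of fibroblasts. Epithelial-mesenchymal transition genes were lower as a set (camera adjusted p = 0.000329, and adjusted p = 0.345 with an estimated correlation), with 6 of 17 lower over all genes, and 11 lower and 1 higher adjusted over the list alone. They included Inhba (13.3 to 9.35 CPM, log2 -1.01, adjusted p = 0.0123) and Cd44 (391 to 320.2 CPM, log2 -0.32, adjusted p = 0.0167). Matrix remodelling enzymes were lower (camera adjusted p = 0.000502, and adjusted p = 0.345 with an estimated correlation), with 4 of 18 lower adjusted over the list alone. The 3 lower over all genes were Has2, Mmp14 (log2 -0.25, adjusted p = 0.0158) and Mmp10 (-1.97, adjusted p = 0.0257). Myofibroblastic CAF markers were lower (camera adjusted p = 7.1e-05, and adjusted p = 0.363 with an estimated correlation), with 6 of 18 lower both over all genes and adjusted over the list alone. Col5a2 was one of them (log2 -1.53, adjusted p = 0.0269), while Acta2 was at log2 0.16 (adjusted p = 0.802). Inflammatory CAF markers were lower by camera (adjusted p = 0.0489, and adjusted p = 0.363 with an estimated correlation), with 5 of 20 lower and 1 higher over all genes. The counts were the same adjusted over the list alone. That last call was lost without KO library 4 (0.116), KO library 11 (0.0538), KO library 7 (0.0923), WT library 6 (0.0919) or WT library 2 (0.0771).

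The fibroblast marker list was itself lower in organoid fractions (camera adjusted p = 2.4e-05, and adjusted p = 0.345 with an estimated correlation), with 5 of 9 lower over all genes and 8 adjusted over the list alone. Its mean was lower in 7 of 7 libraries. Col3a1 was at log2 -2.74 (adjusted p = 0.0355), Bgn at -1.45 (adjusted p = 0.0156) and Sparc at -1.20 (adjusted p = 0.0349), while Pdgfrb was below the expression filter. The PSC share of organoid fractions, estimated from fibroblast markers, was 0.0804% ± 0.056 (SD, n = 4) with WT PSCs and 0.0286% ± 0.0181 (SD, n = 7) with KO PSCs. The log2 difference within co-cultures was -1.36 (exact permutation p = 0.037 over 54 assignments, which treat libraries of 1 PSC line as separate). This difference stood beside the fall of all 10 lists called lower in organoids. The PSC RNA it represents equals 91.0% of the fall of Col1a1, 82.4% of that of Sparc, 137% of that of Col5a2, 125% of that of Col3a1 and 120% of that of Saa3. It equals 1.39% for Has2 and 0.0423% for Ccn2. Col1a1, Sparc and Col3a1 are among the markers that set the share, so for them this is no test, while Col5a2, Saa3, Has2 and Ccn2 are not. With fibroblast markers as a covariate 7 of the 11 list calls were lost. Beside YAP and JAK-STAT3 targets they were the matrix remodelling (camera adjusted p = 0.0501), myofibroblastic CAF (0.342), inflammatory CAF (0.626), fibroblast (0.626) and epithelial-mesenchymal transition lists (0.77). Their median log2 fold changes, in this order, went from -0.28 to -0.251, -0.357 to -0.096, -0.203 to -0.109, -1.195 to -0.107 and -0.732 to 0.004, and the median SEs of their members from between 0.147 and 0.3 to between 0.351 and 0.698. The other 4 were still called. The ATF4 (0.00386) and basal-like lists (0.00318) passed with the covariate, with medians going from -0.069 to -0.095 and from -0.056 to -0.217 and median SEs from 0.062 to 0.142 and from 0.113 to 0.205. Sparc stood at log2 0.05 (adjusted p = 0.991). The covariate is the mean of the fibroblast list, Sparc included, so the loss for Sparc and for that list was given in advance.

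Interferon-stimulated genes were lower as a set in organoids (camera adjusted p = 1.4e-07, and adjusted p = 0.457 with an estimated correlation), with 1 of 33 lower over all genes and adjusted over the list alone. That gene was Mx1, an antiviral GTPase, from 8.45 to 4.73 CPM (log2 -1.08, adjusted p = 0.0227). Ifit3 was at log2 -2.22 (adjusted p = 0.0868), Zbp1 at -2.13 (adjusted p = 0.064) and Stat2 at -0.72 (adjusted p = 0.152). The list mean was lower in 6 of 7 libraries, from -3.21 to 0.58 on the log2 scale. With fibroblast markers as a covariate the list was still called, and the median log2 fold change of its members went from -0.978 to -2.619 with a median SE going from 0.555 to 1.527.

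**Figure D4:**
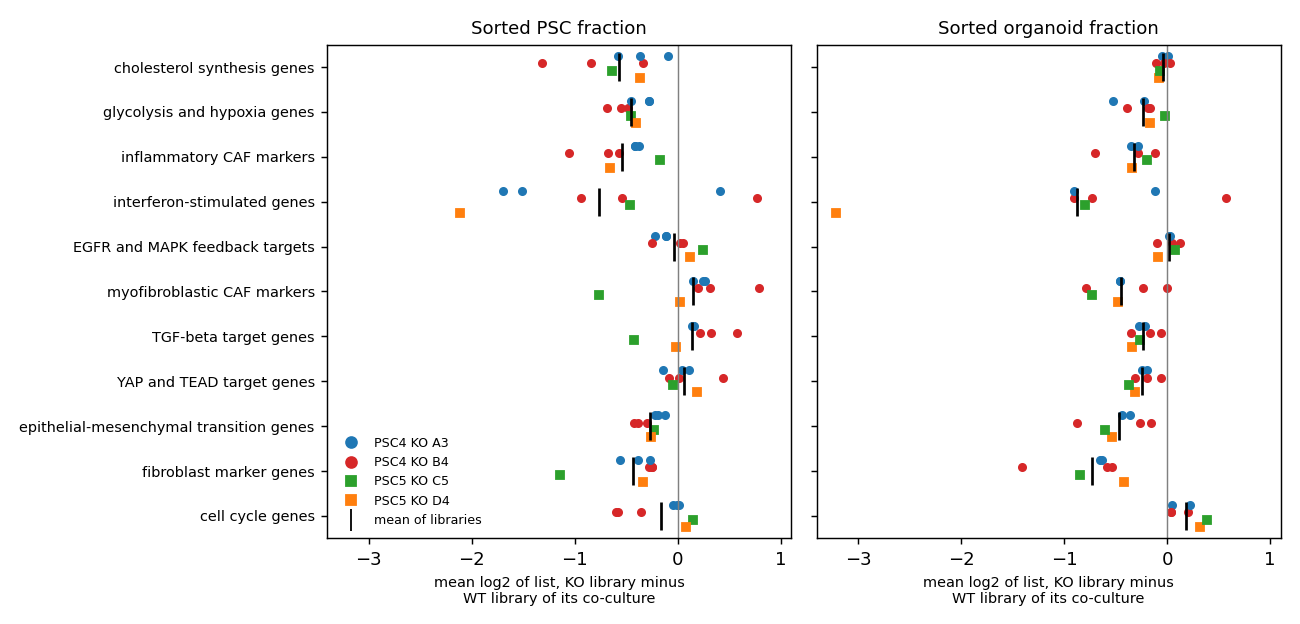
Mean log2 difference of the members of 11 gene lists between each KO library and the WT library of its co-culture (horizontal axis), for the sorted PSC and organoid fractions; each point is 1 library, coloured by KO clone, and the bar is the mean of the libraries. Cell cycle genes lie above 0 in 7 of 7 organoid libraries and cholesterol synthesis genes below 0 in 8 of 8 PSC libraries, while interferon-stimulated genes range from -2.11 to 0.77 in PSC libraries.

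EGFR and MAPK feedback targets did not pass as a set in organoids (median log2 -0.01, camera adjusted p = 0.587 with an upward direction). Of 30 members 2 were higher and 1 lower over all genes, and 3 higher and 4 lower adjusted over the list alone. Egr2 rose from 28.3 to 43.5 CPM (log2 0.66, adjusted p = 0.0242), Egr1 rose (log2 0.23, adjusted p = 0.0483) and Ier3 fell (-0.26, adjusted p = 0.0405). Of 11 EGFR ligands and receptors 0 passed both ways (camera adjusted p = 0.431). Ereg was at log2 0.26 (adjusted p = 0.0679), Hbegf at 0.18 (adjusted p = 0.216), Areg at 0.21 (adjusted p = 0.272) and Btc at -0.12 (adjusted p = 0.372).

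Of p53 targets 4 of 23 fell over all genes, and 2 were higher and 5 lower adjusted over the list alone (camera adjusted p = 0.227). These included the cell cycle inhibitor Cdkn1a, from 127 to 79.4 CPM (log2 -0.70, adjusted p = 0.00473), Ptp4a3 (-0.44, adjusted p = 0.00634) and Phlda3 (-0.32, adjusted p = 0.0253). The classical tumour programme had 2 of 26 higher and 1 lower over all genes, and 6 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.0649). The gut regulator Hnf4a was higher (189 to 222 CPM, log2 0.28, adjusted p = 0.00783) and Foxa3 was lower (-0.39, adjusted p = 0.0345). The basal-like programme had 3 of 20 lower over all genes and 6 adjusted over the list alone (camera adjusted p = 0.0666). They included the desmosomal Dsg3 (11.1 to 5.03 CPM, log2 -1.16, SE 0.16, adjusted p = 0.00344) and Tns4 (642 to 428 CPM, log2 -0.44, adjusted p = 0.00509). Of 25 cholesterol synthesis genes 4 fell over all genes and 5 were lower adjusted over the list alone (camera adjusted p = 0.227), among them Pmvk (log2 -0.28, adjusted p = 0.00783). Of 27 ATF4 and unfolded protein response genes 1 rose and 4 fell over all genes, and 5 were higher and 5 lower adjusted over the list alone (camera adjusted p = 0.535), with Trib3 at log2 -0.54 (adjusted p = 0.0107).

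NF-kappaB targets had 3 of 23 lower over all genes and adjusted over the list alone (camera adjusted p = 0.535), including Relb (log2 -0.42, adjusted p = 0.0144) and Birc3 (-0.34, adjusted p = 0.0179). In the antigen-presenting CAF and mesothelial list 1 of 10 rose both ways, Upk1b (log2 0.80, adjusted p = 0.00844; camera adjusted p = 0.684). In the Wnt and Hedgehog list 1 of 11 rose both ways, Apcdd1 (log2 0.67, adjusted p = 0.0134; camera adjusted p = 0.587). Epithelial markers had 3 of 22 higher both ways (camera adjusted p = 0.557), among them the tight junction gene Ocln (log2 0.18, adjusted p = 0.0437). Epcam was at -0.18 (adjusted p = 0.0658) and Krt19 at 0.08 (adjusted p = 0.503). Among immune markers Cd68, a lysosomal protein of macrophages and other cells, fell from 20.1 to 13.6 CPM (log2 -0.58, adjusted p = 0.00215, lower in 7 of 7). It was 1 of 5 measured that fell over all genes, with 2 of 5 adjusted over the list alone (camera adjusted p = 0.473). Among 7 endothelial markers Flt1 was lower both ways (log2 -0.58, adjusted p = 0.0479; camera adjusted p = 0.227). Acinar and endocrine (3 measured, camera adjusted p = 0.535) and neural and muscle markers (3, adjusted p = 0.785) had 0 members passing both ways.

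The next comparison tested whether the effect of PSC genotype differed between the fractions. It identified 93 of 14753 genes, 52 with a more positive effect in PSCs and 41 with a more negative one, and 2405 at an unadjusted p under 0.05. With culture as a block, which pairs both fractions of 11 cultures, 25 genes passed, 16 of them among the 93, and 2842 had an unadjusted p under 0.05. The median absolute log2 effect of the 93 was 1.042 before and 1.04 with this block, all 93 kept their sign, and the residual degrees of freedom went from 13 to 6. The effect on Aldoc was lower by 3.30 in PSCs than in organoids on the log2 scale (SE 0.33, edgeR adjusted p = 0.00042), being -3.67 in PSCs and -0.31 in organoids (adjusted p = 0.0628). Pdk4 differed by 2.46 (adjusted p = 0.0408). The transcription factor genes Zeb2 and Eomes differed by 2.07 (adjusted p = 0.00879) and 2.74 (adjusted p = 0.0408), and Xlr3b by 1.96 (adjusted p = 0.0497). Cyp1b1, which oxidises steroids and foreign compounds, differed by 1.92 (adjusted p = 0.0134), from 1.21 in PSCs (adjusted p = 0.129) and -0.70 in organoids (adjusted p = 0.00654). In the other direction stood the potassium channel gene Kcnq5 (-4.76, adjusted p = 0.0134), Xkr5 (-3.17, adjusted p = 0.00116) and Miga1 (-2.18, adjusted p = 0.0428). With culture as a block Aldoc (adjusted p = 0.0138), Cyp1b1 and Xkr5 (0.0349 each) passed, and Eomes, Pdk4, Zeb2, Xlr3b, Kcnq5 and Miga1 had an adjusted p of 0.0629 to 0.0999. Pdk4, Zeb2 and Xlr3b were below the expression filter of the organoid test, and Kcnq5 and Xkr5 below that of the PSC test. Egfr itself differed by -0.92 (SE 0.41, adjusted p = 0.279), Col1a1 by 1.43 (adjusted p = 0.11) and Pdgfrb by 2.01 (adjusted p = 0.161). Acta2 differed by 1.02 (adjusted p = 0.496), Epcam by -0.03 and Krt19 by 0.24. The estimate for Il6 was -0.01 with an SE of 6.41, so it leaves the difference for Il6 undetermined.

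By camera 9 lists differed between the fractions, and 0 with an estimated correlation. Lower in PSCs relative to organoids were cholesterol synthesis (adjusted p = 1.4e-11, and adjusted p = 0.33 with an estimated correlation), cell cycle (2.6e-07, then 0.411) and EGFR ligands and receptors (0.011, then 0.33). Higher were TGF-beta targets (0.000179, then 0.33), YAP and TEAD targets (0.00508, then 0.33), myofibroblastic CAF markers (0.00672, then 0.411), fibroblast markers (0.0276, then 0.411), JAK-STAT3 targets (0.0317, then 0.417) and p53 targets (0.0317, then 0.494). The median effects in PSCs and in organoids were -0.085 and -1.195 for fibroblast markers, 0.255 and -0.357 for myofibroblastic CAF markers, 0.185 and -0.294 for TGF-beta targets, 0.129 and -0.185 for YAP and TEAD targets, and -0.007 and -0.153 for JAK-STAT3 targets. Each median covers the members measured in that fraction, so the gene sets differ. In PSCs and organoids these were 23 and 9 fibroblast, 29 and 18 myofibroblastic, and 30 and 23 TGF-beta members. They were 23 and 22 for YAP and TEAD targets, and 17 and 15 for JAK-STAT3 targets. The estimated PSC share of the organoid fractions was lower with KO PSCs (0.0286% against 0.0804%), and the camera test between the fractions has no term for it. In the organoid test the lost PSC RNA equals at least 50% of the fall of 80% of 5 lower fibroblast markers and 66.7% of 6 lower myofibroblastic members, 25% of 4 JAK-STAT3 members, and 0% of the lower TGF-beta and YAP and TEAD members. The PSC share is estimated from the fibroblast markers, with Col1a1 and Col3a1 of the myofibroblastic list among them, so for these genes this is no test. DESeq2 gave 602 genes. The edgeR count was 15 without organoid WT library 14, 17 without PSC WT library 20 or organoid WT library 10, 19 without organoid KO library 4 or WT library 2, 21 without PSC WT library 17 or 23, and 27 without organoid KO library 12. It was 29 without organoid KO library 11, 34 without 16, 37 without 15, and 45 without organoid WT library 6. It was 47 without organoid KO library 7, 143 without PSC KO library 24, 253 without PSC KO library 27 and 385 without PSC WT library 26.

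PSCs and organoids grown together in WT co-cultures were compared to describe what the sort separated. The PSC fraction held fibroblast genes and the organoid fraction epithelial genes, with 8078 of 14416 genes differing (4147 higher in PSCs, 3931 higher in organoids) and 5425 by at least 2-fold. As fitted by edgeR, Col1a1 was 1670-fold higher in PSCs (log2 10.71, adjusted p = 0.000179), Pdgfrb 1680-fold (adjusted p = 3.7e-05), Acta2 389-fold (adjusted p = 0.000212) and Il6 250-fold (adjusted p = 0.000254). Epcam was 535-fold higher in organoids, at 844 CPM against 1.76 CPM (log2 -9.06, adjusted p = 0.000621), and Krt19 135-fold (adjusted p = 0.000212). Egfr was present in both fractions, at 325 CPM in WT PSCs and 113 CPM in their organoids. Genes without a count in 1 fraction gave lower bounds from summed counts, set against 3 counts over the group, which cover counting error only. Dlk1 was at least 1700-fold, Hoxb6 988-fold, Nnmt 943-fold and Tspan11 789-fold higher in PSCs, and Clic6 at least 461-fold, Tmprss11e 415-fold, Bcl11b 288-fold and Hnf4g 258-fold higher in organoids. Ccl7 had 12605 counts in PSCs and 2 in organoids, and Themis3 1 and 2228.

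By camera 14 lists differed between WT fractions, and 0 with an estimated correlation. All 23 measured fibroblast markers were higher in PSCs (adjusted p = 2.9e-12, and adjusted p = 0.421 with an estimated correlation) and all 22 epithelial markers were higher in organoids (camera adjusted p = 1.7e-11). Higher in PSCs were also the matrix (24 higher, 0 lower), epithelial-mesenchymal transition (23 and 1), myofibroblastic CAF (24 and 1), interferon (29 and 1), and inflammatory CAF lists (21 and 2). The same held for the TGF-beta (18 and 3), JAK-STAT3 (12 and 1), cell cycle (18 and 2) and NF-kappaB lists (15 and 6). Higher in organoids were the classical (23 higher there, 0 lower), basal-like (17 and 2) and cholesterol synthesis lists (19 and 0).

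The KO clones of PSC4 and PSC5 were compared for their difference from the WT (Rosa) line of their own PSC parent. The interaction test of edgeR called 0 of 13638 genes, with 654 at an unadjusted p under 0.05, and DESeq2 called 81. The count was 1 without KO library 27 and 2 without KO library 28. In simulated data, with each library drawn by itself, this test recovered 31.4% of genes changed 4-fold and 0% of those changed 2-fold.

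The PSC4 KO clones A3 and B4 were compared with each other over the 3 organoid lines, which shows how far clones of 1 genotype differ. They differed in 6143 of 13595 genes (45.2%), 3041 higher and 3102 lower in A3. Serpine2, a protease inhibitor of the matrix, was at 218 ± 138 CPM in A3 and 1.015 ± 0.708 CPM in B4 (SD, n = 3 each; edgeR adjusted p = 2.6e-05, log2 7.71). Other genes far higher in A3 were the homeobox gene Isl1 (8.92 CPM against 0), Cadm2 (log2 9.33), Crabp1 (8.44), which binds retinoic acid, and Csmd1 (8.21). Genes far lower were Zfp105 (log2 -8.22), Dok5 (-8.12), Chil1 (-7.25), Cntn2 (-7.11) and the transcription factor gene Fli1 (-6.52). Egfr was lower in A3 than in B4, at 89.0 against 179 CPM (log2 -1.02, SE 0.06, adjusted p = 0.000519). Also lower were Acta2 (-0.75, adjusted p = 0.0157), Il6 (-0.59, adjusted p = 0.00542) and Krt19 (-0.64, adjusted p = 0.0332), while Col1a1 was at 0.19 (adjusted p = 0.311). Cell cycle genes (29 of 40 higher in A3) and cholesterol synthesis genes (16 higher, 0 lower) were higher in A3, and interferon-stimulated genes lower (20 lower, 1 higher). Their camera adjusted p was 6.2e-06, 0.000107 and 2.6e-05, with an adjusted p = 0.767 with an estimated correlation for each. The count was 3747 without KO library 19 and 3748 without KO library 18.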

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

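The tests chosen only after the result was seen were the count of splits for the PSC genes, the list calls within co-cultures, the correlation within PSC lines, the thinning of organoid libraries, the assignment of genotypes to whole cultures, the assignments and the shared level of interferon genes, the division of the lower list members by list, and the mitochondrial share by genotype. That share was higher in 7 of 8 KO PSC libraries (2.61% against 2.16%, exact permutation p = 0.037 over 81 assignments), beside the list changes in PSCs. Those assignments treat libraries of 1 PSC line as separate, and the part of this share in the list changes was not tested. Over 70 sets of values, each of 1 measure in a group of 4 to 8 libraries, 8 values from 4 libraries stood far from the others of their group, and chance flags about 1 in 20 groups. Of these, 4 came from organoid KO library 4, the only T69A library grown with KO PSCs that was used, and 1 from its T69A control. In library 4 Egfr stood at 129.4 CPM (others 73.4 to 89.1), Aldh3a1 at 33.65 (7.28 to 17.4), C4bp at 29.27 (0.406 to 1.19) and Pou6f1 at 0.3307 (1.47 to 2.10). In organoid WT library 2 (T69A) C4bp stood at 14.09 CPM (others 0.322 to 0.639). In organoid WT library 10 (T12-LOH) Hist1h2bq stood at 9.084 CPM (others 0.936 to 1.85) and Cxcl10 at 23.03 (1.05 to 3.92). In PSC KO library 28 (clone D4) Aldoc stood at 2.784 CPM (others 0.471 to 1.06).

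The interaction test found 93 genes whose genotype effect differed between PSCs and organoids, among them, as PSC minus organoid log2 effects, Eomes (2.739), Pdk4 (2.461), Zeb2 (2.071), Xlr3b (1.961), Cyp1b1 (1.915), Kcnq5 (-4.76), Aldoc (-3.296), Xkr5 (-3.173) and Miga1 (-2.182). With culture as a block 25 genes passed, and of the genes named here only Aldoc, Cyp1b1 and Xkr5 kept their call. The lists that differed between the fractions by camera were cholesterol synthesis (adjusted p = 1.43e-11), cell cycle (2.624e-07), TGF-beta (0.0001787), YAP and TEAD (0.005076), myofibroblastic CAF (0.006718), EGFR ligands and receptors (0.01096), fibroblast (0.02758), JAK-STAT3 (0.03169) and p53 (0.03169). With an estimated correlation 0 lists passed, and the list tests had no block for culture. The PSC share of organoid fractions was lower with KO PSCs (0.0286% against 0.0804%), so a change in carried-over PSC RNA stays open for the fibroblast, myofibroblastic CAF and JAK-STAT3 lists. With the genotypes assigned to whole cultures, so that both fractions of a culture stay together, 4 of 54 assignments gave as many as the real 93 genes, so chance is not excluded. The other 3 of these, with 2564 genes as the highest, set the 3 cultures of clone B4 apart, which points to a structure of the samples. With the fractions split apart, 4 of 100 splits gave as many (highest other 2025), but those splits do not keep the fractions of a culture together and exclude nothing here.

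The first pattern weighed is that few genes were called in PSCs (9) and many in organoids (1441), although the KO is in the PSCs. Depth is argued against, since organoid libraries thinned to 21731624 counts still gave 1381 genes. Spread between PSC lines of 1 genotype stays open as a candidate explanation, because libraries of 1 PSC line correlated at 0.726 after genotype and co-culture in PSCs, against 0.038 in organoids, and clones A3 and B4 alone differed in 6143 genes. In PSCs 5 of the 81 splits within co-cultures gave as many genes as the real split, so chance is not excluded, and 4 of 100 splits that ignore co-culture did, which exclude nothing here. The highest others gave 4001 and 2887 genes and group the 3 libraries of clone B4, which points to a structure of the samples.

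The second pattern is that 844 genes, with members of matrix and mesenchymal lists, were lower in organoid fractions whose share of PSC RNA was also lower. For the 844 genes as a set, PSC RNA is argued against, since it accounts for at least 50% of the fall in 0.95% of them, and for the higher genes as well, since the lost PSC RNA raises the organoid share by 0.000748 on the log2 scale against a median rise of 0.259. Of 19 lower members of the myofibroblastic, TGF-beta, epithelial-mesenchymal and matrix lists, 26.3% have at least 50% of their fall accounted for, and by list this holds for 66.7% of 6 myofibroblastic members, which is consistent with PSC RNA in the sorted organoid fraction. It holds for 0% of 8 TGF-beta, 6 YAP and TEAD and 3 matrix remodelling members (highest shares 0.509%, 1.2% and 1.39%), which argues against PSC RNA there, and for 33.3% of 6 epithelial-mesenchymal and 25% of 4 JAK-STAT3 members, where it stays open. Col1a1, Col3a1 and Sparc are among the markers that set the PSC share, so their part in these counts is no test. Col5a2 (137%) and Tnc (112%) are not among them. A change in the organoid cells themselves stays open as an untested hypothesis, for the TGF-beta, YAP and TEAD and matrix remodelling members with PSC RNA argued against, and for the other lists beside PSC RNA.

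The third pattern is the lower level of interferon-stimulated genes with KO PSCs in both fractions. Assigning the genotypes at random within co-cultures gave an exact p of 0.136 for the list mean in PSCs (-0.76 over 81 assignments, smallest possible 0.0123) and of 0.13 in organoids (-0.88 over 54, smallest possible 0.0185), so chance is not excluded in either. The list means of both fractions of the same culture, centred per co-culture, went together, with a Pearson r of 0.934 (exact permutation p = 0.00463) and a Spearman rho of 0.909 (exact permutation p = 0.0139) over 11 cultures, the 1 relation computed, and r was 0.874 without the 2 cultures farthest from the median. A level shared by both fractions of a culture is therefore a candidate explanation for that relation, and what sets that level, the genotype included, stays open.

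In organoids 1 of 100 splits, the real one, reached 1441 genes (highest other 556), as did 1 of 54 within co-cultures (highest other 1). A chance split of single libraries is argued against, with a smallest possible share of 0.0185 within co-cultures. These splits treat libraries of 1 PSC line as separate, so chance between the 6 PSC lines is not excluded. Counts summed per PSC line gave 37 genes. For the WT fractions, 1 of the 32 splits that could be fitted, the real one, gave 8078 genes (highest other 0). Every other split mixes PSC and organoid libraries in both groups, so it could hardly give calls and decides little. For clones A3 and B4, 10 splits are too few for a share under 0.05, and 1 of them, the real one, gave 6143 genes (highest other 0). For lists, 73 of 100 splits gave at least 4 called lists in PSCs (highest other 13) and 12 of 100 gave at least 11 in organoids (highest other 14), and within co-cultures 58 of 81 and 12 of 54 did (highest other 14 in both), so chance is not excluded for either number of lists.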

How the results depend on the processing

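The alternatives added after the results were seen are leaving out clone A3 or B4, T6-LOH co-cultures only in the organoid test, summed counts without T69A, limma without the random effect, genes expressed in both fractions, lists with the covariate or without a clone, organoid libraries thinned in depth, culture as a block between the fractions, and Egfr reassigned within co-cultures; the cause of a changed count was not tested unless stated. In PSCs the count of 9 became 4 without the block, 586 by DESeq2, 23 without the low-count filter, 24 with epithelial markers as a covariate, 38 in PSC4 co-cultures only and 45 without clone A3. It was 0 with counts summed per PSC line, with PSC line as a random effect and without T69A, and summing per line and leaving out T69A also leave fewer samples. Leaving out each library gave 0 to 51, and the other alternatives 6 to 13. In organoids the count of 1441 became 0 without the block, 0 with fibroblast markers as a covariate, 867 with a length offset, 37 with counts summed per PSC line, 106 with such sums without T69A, 189 in PSC4 co-cultures only, 445 without T69A, 251 in T6-LOH co-cultures only and 90 with an absolute log2 fold change of at least 1. The covariate shared 81.4% of the genotype's variance and raised the median SE from 0.068 to 0.161 while the median absolute log2 fold change went from 0.304 to 0.299, and 1423 of 1441 genes had the same sign. Leaving out each library gave 214 to 1910, and the other alternatives 990 to 1880.

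The count of 93 between the fractions became 602 by DESeq2 and 54 without the low-count filter, 25 with culture as a block (16 shared; for the 93, all signs kept, median absolute log2 1.042 and 1.04, median SE 0.184 and 0.187, residual degrees of freedom 13 and 6), 91 with RLE size factors, 93 with genes expressed in both fractions, and 15 to 385 leaving out each library. For PSC4 against PSC5, 0 became 81 by DESeq2 and 0 to 2 leaving out each library (0 with T6-LOH only). For clones A3 and B4 leaving out each library gave 3747 to 4809 in place of 6143, with fewer samples, and for WT PSCs and organoids 6307 to 8200 in place of 8078. The 4 lists called in PSCs became 0 with an estimated correlation, 0 by fry, 7 without clone A3 and 4 to 11 leaving out each library. The 11 lists in organoids became 0 with an estimated correlation, 6 with the covariate (4 of them among the 11) and 10 to 13 leaving out each library. Sparc in organoids turned from -1.20 to 0.049 with the fibroblast covariate (adjusted p = 0.991), the only named gene to reverse. Sparc is part of that covariate, so its change was given in advance. Of the values of called named genes under alternatives, 98 kept the call and 84 lost it in PSCs, and 1220 kept it and 801 lost it in organoids, all but Sparc in the same direction. Egfr in PSCs was -1.26 with a pseudocount of 0.1 against -1.25 with 1 and within co-cultures, and in organoids -0.22 within co-cultures against -0.29, with no call changed.

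Groups share no replicate numbers, so pairing came from the titles, as co-culture or culture. Organoid libraries thinned to the lowest PSC depth gave 1381 genes, and genes below the low-count filter were not tested.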

Other observations

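All tests in this part, of organoid lines and of clock genes, and the genes named here were chosen only after the results were seen, while the lists were fixed before. PSC4 lines differed between the co-cultures with different organoid lines. PSC4 grew with each organoid line in 1 co-culture only, so the organoid line cannot be told apart from other differences between these co-cultures. Grown with T12-LOH in place of T6-LOH organoids, PSC4 lines differed in 2506 of 14093 genes, 1202 higher and 1304 lower. The test used 3 libraries each, of the WT line and clones A3 and B4, with PSC line as a block. By camera, myofibroblastic CAF markers (18 members lower, 1 higher; adjusted p = 1.5e-09, and adjusted p = 0.274 with an estimated correlation) and TGF-beta targets (15 and 0; 2.3e-08, then 0.274) were lower. Matrix remodelling enzymes were also lower (10 and 6; 0.00933, then 0.428), as were fibroblast markers (15 and 4; 0.000286, then 0.274). Cell cycle genes (12 members higher, 0 lower; 1.3e-06, then 0.481) and NF-kappaB targets (9 and 0; 0.000735, then 0.481) were higher. Fbn1 (fibrillin, 129 ± 18.5 against 355 ± 36.5 CPM, SD, log2 -1.46, edgeR adjusted p = 0.000197), Col11a1 (log2 -1.84, adjusted p = 0.000197), Postn (-2.87, adjusted p = 0.0135) and Fmod (1.89 against 96.9 CPM, adjusted p = 0.00326) were lower. So were Acta2 (123 against 451 CPM, log2 -2.18, adjusted p = 0.0175), Tagln (-2.11, adjusted p = 0.0477) and Col1a1 (-0.81, adjusted p = 0.00482). Higher were the acute phase gene Saa3 (10390 ± 2784 against 1875 ± 1385 CPM, log2 2.73, adjusted p = 0.00433), Lcn2 (1.83, adjusted p = 0.00673), and the collagenase gene Mmp13 (3.10, adjusted p = 0.00843). Also higher were the cytokine genes Csf3 (3.28, adjusted p = 0.00466) and Il6 (161 against 61.3 CPM, log2 1.60, adjusted p = 0.0253), the chemokine gene Cxcl1 (1.03, adjusted p = 0.0447) and Nos2 (2.30, adjusted p = 0.00221). The count was 902 without KO library 21, 919 without KO library 24 and 1168 without WT library 20.

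Grown with T69A in place of T6-LOH organoids, PSC4 lines differed in 607 genes, 402 higher and 205 lower. Saa3 (log2 1.83, edgeR adjusted p = 0.0388), Nos2 (2.06, adjusted p = 0.0204) and Lcn2 (1.58, adjusted p = 0.0351) were higher, while Acta2 was at -1.25 (adjusted p = 0.109). Epithelial markers had 10 higher and 0 lower (camera adjusted p = 5.2e-13, and adjusted p = 0.512 with an estimated correlation), beside an organoid share of 0.549 to 0.72% in the T69A libraries. The count was 1 without KO library 18, 3 without KO library 21, 6 without KO library 19 or WT library 17, 57 without WT library 20, 83 without KO library 22, 214 without KO library 24 and 1136 by DESeq2. Each of these comparisons allows 10 splits, too few for a share under 0.05, and 1 split, the real one, gave as many genes as 2506 and 607 (highest other 0 in both).

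Beside Nr1d1, which rose in KO PSCs, other clock genes were looked at after its value was seen. Per2 was at log2 0.67 (edgeR adjusted p = 0.212, higher in 8 of 8 KO libraries), Dbp at 0.58 (adjusted p = 0.278, higher in 7 of 8) and Arntl at -0.11 (adjusted p = 0.657), so none of these 3 passed.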
